A study of Mus musculus with 9 samples.

How the data were processed

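RNA of pooled aortas from 9 pools (3 groups of 3, 3 aortas per pool) was labelled with the FL-Ovation kit and biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The authors deposited 1 table of log2 signals for 45101 probe sets, made with RMA per the submitters' processing notes; RMA corrects background, quantile normalizes probes and summarises probe sets on the log2 scale, and its version is not given in the sources used here. That the values are log2 was read from their range. RMA makes the arrays' distributions alike, so a change shared by most genes would not be seen. Replicate numbers come from the labels, and the pools are described as separate groups of aortas. The groups share only the numbers 3 and 4, and no label says that a replicate number marks a shared batch. The sample titles end in running numbers that do not interleave between the groups. What these mark is not stated. If they follow the order of processing, order cannot be told apart from group in any comparison.

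Gene names came from the platform annotation, which gave 1 gene for 34945 probe sets, several for 932 and none for 9160, with 64 control probe sets besides; 34754 were matched by gene identifier to RefSeq genes of assembly GRCm38.p6, used for names only. Each gene was represented by the probe set with the highest mean over all arrays, among probe sets with 1 gene, which left 18193 genes; no filter on dim genes was used. Linear models were fitted over all 9 arrays with lmFit and eBayes (limma 3.58.1, R 4.3.3), so that the groups shared 1 estimate of each gene's spread with 6 residual degrees of freedom, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1. Figures were drawn with matplotlib 3.10.9.

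There were 29 gene lists (487 genes, 450 of them measured, 3 through a synonym) for lesion cells, lipid handling, inflammation, the vector response and other tissues. They were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation, with fry and on ranks. Among the lists called in any comparison, the mean pairwise correlation of members within groups ran from 0.055 (smooth muscle) to 0.75 (oxidative phosphorylation). These values lie above the preset, so camera p at the preset is likely too small for these lists. A list is said below to shift if it passed at the preset. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names Apoe, Il7 and Il7r; per comparison and direction the 10 genes past the threshold with the largest change and non-overlapping groups, filled with the smallest unadjusted p among brighter genes; and, for each list that shifted, up to 4 called members or else the 3 with the smallest p. Unnamed clones were counted but skipped. Not all genes the rule names are printed. The list genes without a usable probe set are not analysed here.

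The procedure was tested on simulated data for HDAd-gE3 against HDAd-0 with 18193 genes, 10 simulations and 200 changed genes in each: 52.7% of genes changed by a log2 size of 0.5, 89.3% at 1 and 96.9% at 2 were called, and 4.32% of called genes were unchanged. With 200 changed genes the adjusted threshold is looser than in the real comparison, where 1 gene passed, so these shares do not hold there. All lists shifted by 0.3 and 0.37% of unshifted lists were called. The simulated genes varied independently, which the genes of the real lists do not.

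Alternatives were other scalings, a filter on dim genes, other choices of probe set, a replicate block, array weights, an intensity trend, other thresholds, only the 2 groups compared, other list tests and leaving out each array. A covariate for the 3' minus 5' control signal and a fit without HDAd-gE3 replicate 4 and HDAd-0 replicate 5 were chosen after seeing the data. Of the tests in the closing section, the one on neutrophil genes in HDAd-0 was first run on 4 genes picked by hand instead of the whole neutrophil list that had been written down, and the coherence test of tissue lists was first run with a limit of 0.3 instead of 0.5 as written down; both were put back as written after the results had been seen, and the closing section gives both versions where the outcome differed. The test of 5 neutrophil precursor genes in HDAd-gE3 met the condition written for it, a rise over 2 SE. It was first counted for that source and set to undecided after the result had been seen, because neutrophil genes had been seen to be higher there before the test was written.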

Results

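Gene expression was measured in the aorta of female mice lacking apolipoprotein E (Apoe), which develop atherosclerosis, after 30 weeks on a diet with 0.2% cholesterol and 10% coconut oil. The mice received 1 tail-vein injection and were killed 10 days later. The injection held a helper-dependent adenovirus (an adenoviral vector stripped of its viral genes) carrying human apolipoprotein E3 (HDAd-gE3), the same kind of vector without the transgene (HDAd-0), or phosphate-buffered saline (PBS). Each of the 9 arrays measured RNA pooled from 3 aortas, taken from the sinus to the arch, and each group had 3 arrays. The series title names interleukin-7 and the arrest of monocytes and macrophages on endothelium. The deposited log2 signals ran from 1.98 to 14.7, the array medians from 6.67 to 6.77, and no pair of arrays correlated below 0.991 across probe sets. The 3 arrays per group limit the precision of every value. The mean log2 difference between 3' and 5' control probe sets of Actb and Gapdh, a sign of RNA quality, was 0.735 ± 0.069 (SD, n = 3) with HDAd-gE3, 0.933 ± 0.16 with HDAd-0 and 0.866 ± 0.071 with PBS.

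The Apoe probe set read 6.95 ± 0.20 with HDAd-gE3, 7.32 ± 0.28 with HDAd-0 and 6.88 ± 0.14 with PBS (log2, SD, n = 3). All mice were knockouts and the vector carried the human gene, so this mouse probe set does not test the labels, and it passed the limma threshold in none of the 3 comparisons (adjusted p = 0.373, 0.305 and 0.892). Il7, which encodes the cytokine interleukin-7, read 7.46 ± 0.07 with HDAd-gE3, 7.70 ± 0.15 with HDAd-0 and 7.65 ± 0.12 with PBS. Its difference between HDAd-gE3 and HDAd-0 was -0.24 ± 0.094 (SE), which did not pass (limma, adjusted p = 0.362). A second, dimmer Il7 probe set differed by -0.48 ± 0.098 in the same direction (limma over every probe set, adjusted p = 0.197), and by 0.38 ± 0.098 between HDAd-0 and PBS. Il7r, the interleukin-7 receptor alpha chain, read 11.87 ± 0.04, 12.05 ± 0.11 and 12.14 ± 0.07 in the same order of groups. All 3 HDAd-gE3 arrays lay below all 3 PBS arrays, with a difference of -0.27 ± 0.071 that missed the threshold over all genes (limma, adjusted p = 0.205). None of the 14 measured genes of the interleukin-7 list passed over all genes in any comparison, while 1 was higher and 4 lower at an unadjusted p under 0.05 in HDAd-gE3 against HDAd-0. Adjusted over the list alone, Il7r (lower) and Jak1 (higher, 0.23 ± 0.059; named after its value was seen) passed in HDAd-gE3 against PBS. Since the series concerns interleukin-7, this list may not be independent of these samples. The list did not shift in any comparison (camera, adjusted p = 0.86 against HDAd-0, 0.947 against PBS, and 0.936 for HDAd-0 against PBS).

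**Figure D1:**
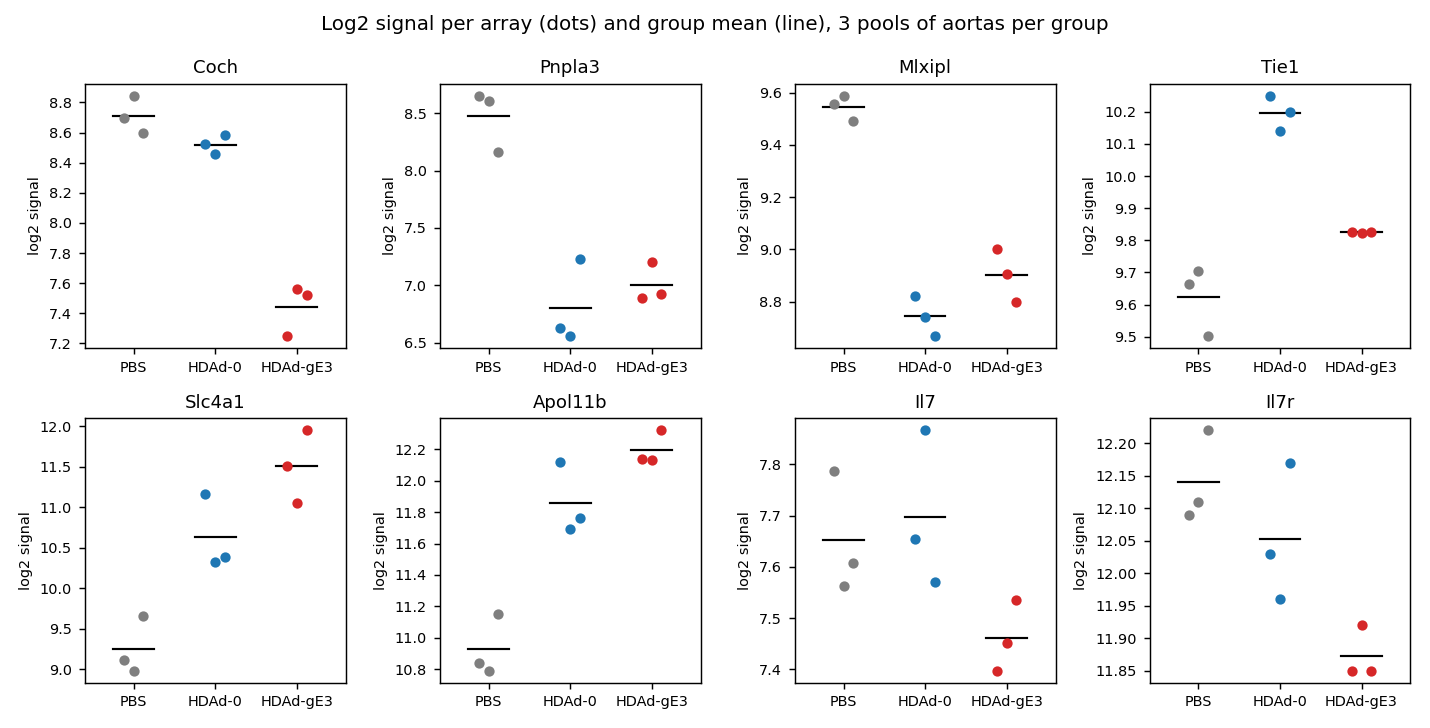
Log2 signal (vertical axis) of 8 named genes on each array (dots) with the group mean (line) for PBS, HDAd-0 and HDAd-gE3 (horizontal axis). Coch sits at 7.44 with HDAd-gE3 against 8.52 with HDAd-0 and 8.71 with PBS, while Pnpla3 and Mlxipl are lower in both vector groups than with PBS; each panel has its own vertical range, which does not start at 0.

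The comparison of HDAd-gE3 with HDAd-0 asks what the apolipoprotein E3 cassette adds to the vector. Coch, which encodes the secreted protein cochlin, was 2.11-fold lower with HDAd-gE3, at 7.44 ± 0.17 against 8.52 ± 0.062 (log2, SD, n = 3), a change of -1.08 ± 0.099 (SE; limma, adjusted p = 0.0486). It was the only 1 of 18193 genes past the threshold, and 2340 genes (12.9%) had an unadjusted p under 0.05. The 3 arrays of each group did not overlap for 16.3% of genes, where chance gives 10%. Genes of monocytes and macrophages were lower with HDAd-gE3 as a group: 23 of 24 measured members had a lower mean and the list shifted down by a median of -0.16 (camera, adjusted p = 4.04e-06; adjusted p = 0.31 with an estimated correlation). None of its members passed singly, over all genes or over the list alone, and 11 were lower at an unadjusted p under 0.05. Aif1, a macrophage calcium-binding protein, differed by -0.35 ± 0.083, Ms4a7 by -0.22 ± 0.063 and Mpeg1, a pore-forming protein of macrophages, by -0.17 ± 0.05, with limma adjusted p of 0.206, 0.265 and 0.264.

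Chemokines and their receptors also shifted down, with 22 of 23 members lower and a median of -0.27 (camera, adjusted p = 0.000248; adjusted p = 0.31 with an estimated correlation). Among them Ccl8 differed by -0.27 ± 0.085, Ccl9 by -0.20 ± 0.056 and Ccl20, near the floor at 4.04, by -0.19 ± 0.052, none past the limma threshold. Leukocyte adhesion genes shifted down (12 of 15 lower; camera, adjusted p = 0.0167; adjusted p = 0.36 with an estimated correlation), and adjusted over the list alone 6 members were lower and 1 higher, against 0 over all genes. P-selectin (Selp) differed by -0.38 ± 0.069, its ligand Selplg by -0.27 ± 0.057 and E-selectin (Sele) by -0.49 ± 0.11, with limma adjusted p of 0.191, 0.196 and 0.196. Endothelial genes shifted down (13 of 16; camera, adjusted p = 0.00435; adjusted p = 0.36 with an estimated correlation), and 6 passed adjusted over the list alone, with Vwf, the von Willebrand factor, at -0.38 ± 0.064, the receptor Tie1 at -0.37 ± 0.066 and Tek at -0.32 ± 0.077. MHC class II genes (10 of 11 lower, median -0.21) and interferon-stimulated genes (21 of 25 lower, median -0.14) shifted down with camera adjusted p of 0.0137 and 0.0167. With an estimated correlation they gave an adjusted p of 0.54 and 0.67. H2-Ab1 differed by -0.35 ± 0.077 and Oas1a by -0.30 ± 0.085, neither past the limma threshold. Several of these list calls rested on single arrays. Without HDAd-gE3 replicate 2 the adhesion, interferon-stimulated and MHC class II lists lost their calls (camera, adjusted p = 0.15, 0.071 and 0.18). Without HDAd-0 replicate 5 the same 3 lists lost them (0.15, 0.96 and 0.32), and without HDAd-gE3 replicate 4 the interferon-stimulated and endothelial lists did (0.058 and 0.098). The MHC class II median was -0.139 without HDAd-gE3 replicate 2 and -0.0847 without HDAd-0 replicate 5, where the interferon-stimulated median was -0.0303. The interferon-stimulated median stayed near its main value without HDAd-gE3 replicate 2 (-0.125) and without HDAd-gE3 replicate 4 (-0.154). The endothelial median was -0.137 without HDAd-gE3 replicate 4, against -0.217. The macrophage and chemokine calls held without any 1 array, but array weights ended the chemokine call (median -0.132; camera, adjusted p = 0.073) and the adhesion and MHC class II calls (0.13 and 0.077). A block for replicate number ended the chemokine, adhesion, interferon-stimulated and MHC class II calls (camera, adjusted p = 0.24, 0.52, 0.79 and 0.83). The adhesion call was lost on ranks as well (0.058), and the interferon-stimulated and MHC class II calls by fry (adjusted p = 0.28 and 0.16). In other fits the interferon-stimulated and MHC class II medians were larger, at -0.334 and -0.361 with the 3' minus 5' control signal as a covariate (chosen after seeing the data; camera, adjusted p = 2.1e-11 and 0.00017) and -0.282 and -0.327 without HDAd-0 replicate 4, where the chemokine median was -0.173.

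Markers of other tissues and of the aortic wall moved in the same comparison. Liver genes (11 of 11 lower, median -0.84) and skeletal muscle genes (12 of 14 lower, median -0.97) shifted down with camera adjusted p of 0.000119 and 0.00293. Both lost the call (adjusted p = 0.36 and 0.53 with an estimated correlation). The skeletal muscle call was lost without HDAd-0 replicate 5 (camera, adjusted p = 0.2) or HDAd-gE3 replicate 4 (0.058), and by fry neither list passed (adjusted p = 0.18, and 0.099 for liver). The liver median was -0.397 without HDAd-0 replicate 5 (camera, adjusted p = 0.023), -0.499 with array weights and -1.55 with the covariate, where that of skeletal muscle was -1.52. Without HDAd-0 replicate 5 the skeletal muscle median was -0.542, and without HDAd-gE3 replicate 4 it was -0.857. Among the members the fast myosin gene Myh2 differed by -1.81 ± 0.43 and fibrinogen beta (Fgb) by -1.07 ± 0.35, with SDs of 1.1 and 0.81 among the HDAd-0 arrays. Cardiac muscle genes shifted up (13 of 15 higher, median 0.40; camera, adjusted p = 1.38e-06; adjusted p = 0.36 with an estimated correlation), with atrial natriuretic peptide (Nppa) at 1.58 ± 0.42. The cardiac list mean was 0.74, 0.219 and -0.502 on HDAd-gE3 replicates 2, 3 and 4. Its median difference was 0.207 without HDAd-gE3 replicate 2, 0.245 without HDAd-0 replicate 3, 0.622 without HDAd-0 replicate 4 and 0.875 without HDAd-gE3 replicate 4, and fry did not call it (adjusted p = 0.3). Neutrophil genes shifted up (11 of 12 higher, median 0.61; camera, adjusted p = 1.24e-07; adjusted p = 0.31 with an estimated correlation), and 6 passed adjusted over the list alone. The granule genes Ngp and Ltf were 2.02 ± 0.45 and 1.92 ± 0.44 higher in mean, and S100a9 0.58 ± 0.14, none past the limma threshold. The neutrophil list mean was 1.29 on HDAd-gE3 replicate 4 against 0.226 and 0.427 on the others of its group, relative to the mean of all arrays. Its median difference was 1.01 with the covariate and 0.282 without that array and HDAd-0 replicate 5, and fry did not call it (adjusted p = 0.086). Erythroid (5 of 6 higher), smooth muscle contractile (15 of 15 higher), cartilage and bone (9 of 13), extracellular matrix (17 of 21), oxidative phosphorylation (17 of 19) and adipose genes (8 of 13) shifted up as well. Their camera adjusted p were 0.00293, 3.99e-05, 0.00482, 0.0365, 0.000785 and 0.0437. With an estimated correlation their adjusted p were 0.31, 0.31, 0.48, 0.75, 0.59 and 0.72. Leaving out HDAd-0 replicate 4 ended the cartilage and bone, oxidative phosphorylation and adipose calls (camera, adjusted p = 0.28, 0.083 and 0.99). Leaving out HDAd-gE3 replicate 2 ended the last 2 of these (0.15 and 0.27) and HDAd-gE3 replicate 3 the adipose call (0.13). The extracellular matrix call was lost without HDAd-gE3 replicate 3, HDAd-gE3 replicate 4, HDAd-0 replicate 3 or HDAd-0 replicate 5 (0.095, 0.18, 0.9 and 0.17). The erythroid call was lost with array weights (0.064) and by fry (0.12), and its median of 0.747 was 0.481 without HDAd-gE3 replicate 4. The replicate block ended the liver, skeletal muscle and erythroid calls (camera, adjusted p = 0.067, 0.095 and 0.058). A filter on dim genes ended the extracellular matrix, cartilage and bone, and adipose calls (0.15, 0.082 and 0.15). The adipose call was also lost with median centring, the mean of probe sets and array weights (0.056, 0.092 and 0.18). By fry the extracellular matrix, cartilage and bone, adipose and oxidative phosphorylation lists did not pass (adjusted p = 0.72, 0.43, 0.72 and 0.53). The smooth muscle list passed fry (higher, adjusted p = 0.0085). So did the macrophage, adhesion, chemokine and endothelial lists (lower, fry adjusted p = 0.0085, 0.021, 0.035 and 0.029). With the 3' minus 5' covariate the cardiac, cartilage and bone, and oxidative phosphorylation calls were lost (camera, adjusted p = 0.056, 0.91 and 0.93), the cardiac median was 0.20, and the adipose list shifted down instead (0.049). The remaining lists did not pass camera. They were foam cell and lysosome (camera, adjusted p = 0.0522), cholesterol biosynthesis, LXR targets and inflammatory cytokines (each 0.0536), T and NK cell, matrix proteases and the unfolded protein response (each 0.714), B and plasma cell (0.918), thymus and proliferation (each 0.786), nerve and Schwann cell (0.729) and immediate early genes (0.619). Foam cell and lysosome genes passed on ranks (lower, adjusted p = 0.025) and by fry (0.027), and LXR targets and inflammatory cytokines by fry (lower, adjusted p = 0.021 and 0.025). Fry tests a list against no change, not against the other genes. The median difference of all genes was -0.0397 here and 0.0244 in HDAd-0 against PBS. Adjusted over the list alone, 3 LXR targets and 1 cytokine, 1 B and plasma cell and 1 unfolded protein response gene were lower.

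Other genes with the smallest p did not pass. Aoah, a lipase that inactivates endotoxin, differed by -0.59 ± 0.073, Cd55 by -0.52 ± 0.085, the gap junction gene Gja4 by -0.52 ± 0.087 and Aldh3a1 by -0.54 ± 0.083, each with a limma adjusted p of 0.191. In the other direction Akap6 differed by 0.61 ± 0.12, P3h2 by 0.57 ± 0.11, Cap2 by 0.52 ± 0.085 and Ramp1 by 0.44 ± 0.083 at the same adjusted p. The Coch call was lost when any 1 of 8 arrays was left out, with adjusted p between 0.0898 and 0.211 (limma), while the change itself stayed between -0.979 and -1.13. Without HDAd-0 replicate 4, the ninth, there were 10 calls, Coch among them. Another fit, chosen after seeing the data, left out HDAd-gE3 replicate 4, the highest array in neutrophil and erythroid genes, and HDAd-0 replicate 5, the highest in liver and skeletal muscle genes. There 1 gene passed, which was not Coch. In that fit 10 lists shifted, against 16 with all arrays, and the endothelial, adhesion, MHC class II, interferon-stimulated, liver and skeletal muscle lists were not among them.

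The comparison of HDAd-0 with PBS sets the vector without the transgene against the vehicle. The hour of killing is not given in the labels, so the groups may differ in it. Pnpla3, a lipid droplet protein, was 3.17-fold lower with HDAd-0, at 6.81 ± 0.37 against 8.47 ± 0.27 (log2, SD, n = 3; change -1.67 ± 0.20, SE; limma, adjusted p = 0.0466). Mlxipl, a glucose-responsive transcription factor (ChREBP), was 1.74-fold lower (-0.80 ± 0.071; limma, adjusted p = 0.0384). The endothelial genes Tie1 (0.57 ± 0.066) and Esam (0.58 ± 0.072) were each 1.49-fold higher, and S1pr1, a sphingosine-1-phosphate receptor, was 1.46-fold higher (0.55 ± 0.058), with limma adjusted p of 0.0466, 0.0478 and 0.0466. In all 12 genes passed, 9 higher and 3 lower, 2346 (12.9%) had an unadjusted p under 0.05, and the groups did not overlap for 18.8% of genes (chance 10%). Sphk2, a sphingosine kinase, rose by 0.65 ± 0.067 on its brighter probe set, but a second one differed by -0.07 ± 0.092, and by -0.30 ± 0.092 between HDAd-gE3 and PBS. Col23a1 rose by 0.62 ± 0.07 and its 2 other probe sets leaned the same way. Fgf14 rose by 0.53 ± 0.067 on its brightest probe set, while the mean over its probe sets, of which the others are dim, fell below that of PBS. H60c and Morn3 rose by 0.53 ± 0.066 and 0.45 ± 0.054 at low signal (4.50 and 5.72 with HDAd-0).

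Endothelial genes shifted up as a group, 14 of 16 higher with a median of 0.38 (camera, adjusted p = 5.31e-09; adjusted p = 0.33 with an estimated correlation); 2 members passed over all genes and 11 adjusted over the list alone. MHC class II genes (10 of 11 higher, median 0.36) and interferon-stimulated genes (23 of 25 higher, median 0.23) shifted up with camera adjusted p of 7.41e-05 and 7.97e-05. Both lost the call (adjusted p = 0.35 and 0.52 with an estimated correlation). The interferon-stimulated call was lost without HDAd-0 replicate 5 (median 0.0929; camera, adjusted p = 0.15). The class II transactivator Ciita differed by 0.78 ± 0.11 (limma, adjusted p = 0.0668), H2-Ab1 by 0.40 ± 0.077 and the antiviral gene Rsad2 by 0.49 ± 0.12, none past the threshold. Rsad2 was not lower with HDAd-gE3, at 12.84, 12.78 and 12.7 against 12.79, 12.33 and 12.54 on the HDAd-0 arrays. Leukocyte adhesion genes (13 of 15 higher; F11r at 0.46 ± 0.086) and macrophage genes (18 of 24 higher; Ccr2, the receptor that recruits monocytes, at 0.59 ± 0.11) shifted up with camera adjusted p of 0.00242 and 0.0302. With an estimated correlation they gave an adjusted p of 0.35 and 0.52. The macrophage call was lost without HDAd-0 replicate 4, HDAd-0 replicate 5, PBS replicate 1 or PBS replicate 3 (camera, adjusted p = 0.12, 0.15, 0.13 and 0.052). It was also lost with quantile normalization (0.07), median centring (0.09), a filter on dim genes (0.061), the mean of probe sets (0.12), without probe sets that may match several transcripts (0.11) and on ranks (0.058). Unfolded protein response genes shifted down (12 of 15; camera, adjusted p = 1.03e-05; adjusted p = 0.35 with an estimated correlation), with Creld2 at -0.59 ± 0.097 and Sdf2l1 at -0.45 ± 0.066, neither past the limma threshold here. Because both comparisons use the HDAd-0 arrays, a list that is high on those arrays shifts up here and down in HDAd-gE3 against HDAd-0, so the opposite shifts are not separate observations.

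Markers of other tissues moved here too. Liver genes were higher in 11 of 11 members (median 1.23; camera, adjusted p = 1.02e-06), with albumin (Alb) at 10.63 ± 1.1 against 8.41 ± 0.30, and skeletal muscle genes in 11 of 14 (median 0.89; camera, adjusted p = 0.00242), while cardiac genes were lower in 15 of 15 (median -0.76; camera, adjusted p = 4.06e-09). With an estimated correlation these gave an adjusted p of 0.35, 0.52 and 0.35. Without HDAd-0 replicate 5 the skeletal muscle call was lost (median 0.34; camera, adjusted p = 0.15), while without HDAd-0 replicate 3 the median was 1.35. The liver list mean was 1.27 and the skeletal muscle mean 1.41 on HDAd-0 replicate 5, against 0.0455 and -0.248 on HDAd-0 replicate 3. Erythroid genes shifted up (5 of 6, median 0.87; camera, adjusted p = 0.00267; adjusted p = 0.35 with an estimated correlation), with the anion exchanger Slc4a1 at 1.38 ± 0.29. Proliferation (16 of 17), immediate early (14 of 17; Nr4a1 at 0.85 ± 0.21) and B and plasma cell genes (12 of 14) shifted up with camera adjusted p of 0.00906, 0.0131 and 0.0476. Smooth muscle contractile (12 of 15 lower), cartilage and bone (11 of 13 lower) and oxidative phosphorylation genes (17 of 19 lower) shifted down at 0.0101, 0.000155 and 0.0247. For these 6 lists an estimated correlation gave an adjusted p of 0.73, 0.52, 0.59, 0.35, 0.35 and 0.84. Single arrays ended the proliferation call (HDAd-0 replicate 5; camera, adjusted p = 0.24) and the immediate early call (HDAd-0 replicate 4; 0.33). The oxidative phosphorylation call was lost without HDAd-0 replicate 4, PBS replicate 1 or PBS replicate 3 (0.46, 0.24 and 0.098). The B and plasma cell call was lost without HDAd-gE3 replicate 3, HDAd-0 replicate 3, HDAd-0 replicate 5, PBS replicate 1 or PBS replicate 3 (0.055, 0.078, 0.21, 0.24 and 0.08). The 3' minus 5' covariate ended the B and plasma cell, immediate early and oxidative phosphorylation calls (camera, adjusted p = 0.12, 0.1 and 0.27). Array weights ended the immediate early call (0.071) and a filter on dim genes the oxidative phosphorylation call (0.071). The replicate block ended the macrophage, interferon-stimulated, B and plasma cell, smooth muscle and skeletal muscle calls (camera, adjusted p = 0.3, 0.075, 0.34, 0.075 and 0.13). It also ended the erythroid, proliferation, immediate early and oxidative phosphorylation calls (0.062, 0.22, 0.06 and 0.056). By fry 11 of the 16 lists did not pass: interferon-stimulated, MHC class II, B and plasma cell, smooth muscle, cartilage and bone, cardiac, skeletal muscle, liver, proliferation, immediate early and oxidative phosphorylation (adjusted p = 0.18, 0.058, 0.26, 0.12, 0.18, 0.17, 0.23, 0.058, 0.38, 0.17 and 0.68). Without HDAd-0 replicate 5 the smooth muscle median was -0.0103 against -0.0591, without HDAd-0 replicate 4 that of cartilage and bone -0.271 against -0.493, and without HDAd-0 replicate 3 that of the unfolded protein response -0.0819 against -0.141. The other 13 lists did not pass camera, neutrophil genes among them (camera, adjusted p = 0.534), with cholesterol biosynthesis nearest to the threshold (0.194). Adjusted over the list alone, 1 chemokine gene was lower and 1 adipose gene higher. Leaving out 1 array at a time gave limma counts between 0 and 31 genes. They were 31 without HDAd-0 replicate 4, 3 without HDAd-0 replicate 5 and 0 in the other 7 cases, with between 1669 and 2412 genes at an unadjusted p under 0.05 in those 7. Without HDAd-gE3 replicate 4 and HDAd-0 replicate 5 together, 1 gene passed that was not among the 12, and 15 lists shifted.

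**Figure D2:**
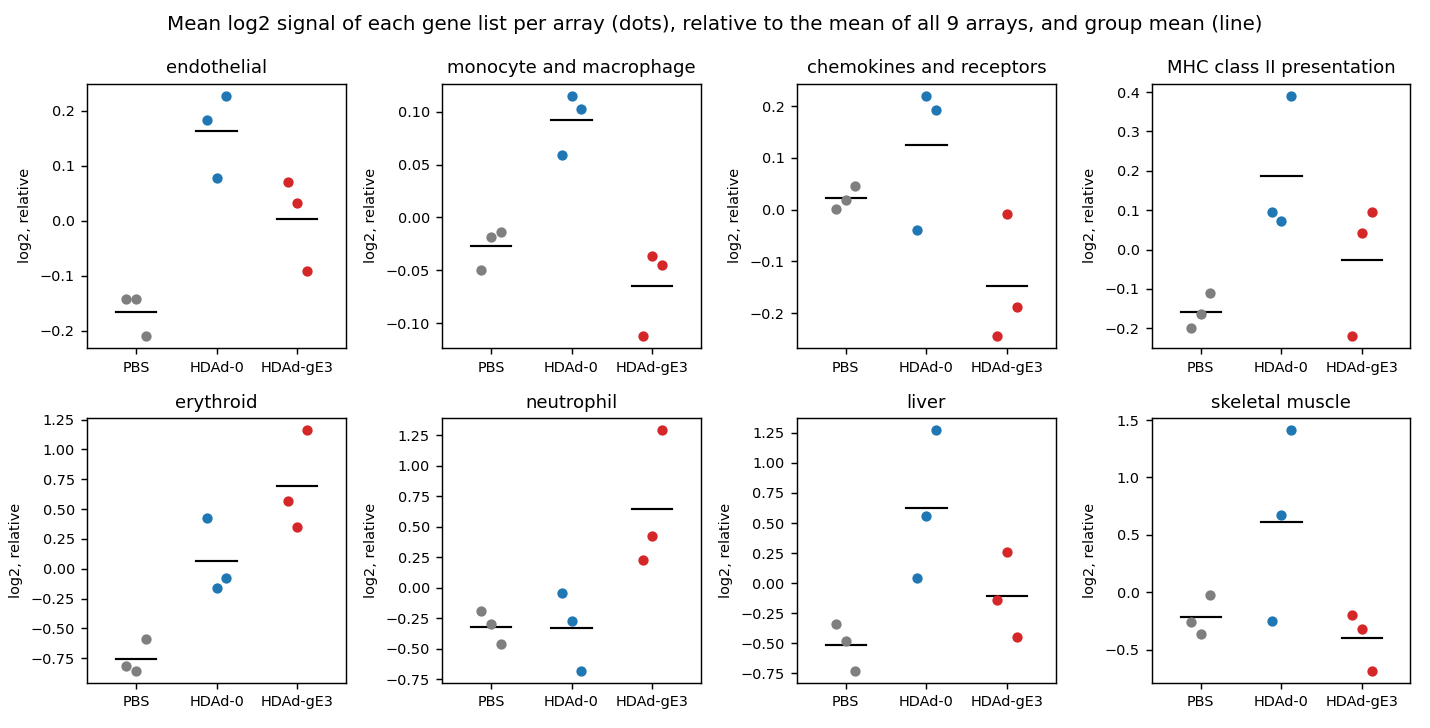
Mean log2 signal of 8 gene lists (vertical axis, relative to the mean of all 9 arrays) on each array (dots) with the group mean (line) for PBS, HDAd-0 and HDAd-gE3 (horizontal axis). Liver and skeletal muscle lists reach 1.27 and 1.41 on HDAd-0 replicate 5 and the neutrophil list reaches 1.29 on HDAd-gE3 replicate 4; vertical ranges differ between panels.

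The comparison of HDAd-gE3 with PBS sets the full treatment against the vehicle. Among the genes past the threshold the largest increases were in Trim10, which rose 5.55-fold (2.47 ± 0.32, SE), Slc4a1, the red cell anion exchanger, 4.76-fold (2.25 ± 0.29), carbonic anhydrase 2 (Car2) 3.23-fold (1.69 ± 0.21) and Apol11b 2.42-fold (1.27 ± 0.13), with limma adjusted p of 0.0371, 0.0386, 0.0369 and 0.031. The mitochondrial iron carrier Slc25a37 rose 1.87-fold (0.90 ± 0.12; limma, adjusted p = 0.037). Coch was 2.41-fold lower (-1.27 ± 0.099; limma, adjusted p = 0.0129), Pnpla3 2.76-fold lower (-1.47 ± 0.20), the chemokine Ccl24 2.30-fold lower (-1.20 ± 0.14), Aoah 1.58-fold lower (-0.66 ± 0.073) and Mlxipl 1.56-fold lower (-0.64 ± 0.071). In all 23 genes passed, 14 higher and 9 lower, 2402 (13.2%) had an unadjusted p under 0.05, and the groups did not overlap for 23.9% of genes (chance 10%). All 23 also differed in the same direction in HDAd-0 against PBS, a comparison that uses the same PBS arrays. Fam117a (0.79 ± 0.10), Camk2b (0.74 ± 0.085), Lrrc17 (0.71 ± 0.086), Pcp4l1 (0.69 ± 0.094) and Ccndbp1 (0.66 ± 0.08) rose too, while Lonrf3 (-0.71 ± 0.079), the endoplasmic reticulum gene Sdf2l1 (-0.48 ± 0.066) and the Hsp90 partner Chordc1 (-0.48 ± 0.062) fell. As the mean of their probe sets, Aoah (3 probe sets, the dimmest at 0.222 ± 0.13) differed by -0.317 and Lrrc17 (a second, dim one at -0.0846 ± 0.094) by 0.315, neither past the limma threshold.

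Erythroid genes shifted up as a group (5 of 6 higher, median 1.63; camera, adjusted p = 1.27e-05; adjusted p = 0.32 with an estimated correlation); 2 members passed over all genes, and adjusted over the list alone 5 were higher and 1 lower. The lower 1 was Hba-a1, read only near the floor. Probe sets naming several genes were not used, so this reading may not give the level of the gene. Neutrophil genes shifted up (11 of 12 higher; camera, adjusted p = 1.07e-05; adjusted p = 0.53 with an estimated correlation), with the granule peptide gene Camp at 2.36 ± 0.58 and an SD of 1.4 among the HDAd-gE3 arrays, and 6 passed adjusted over the list alone. Endothelial genes shifted up (14 of 16 higher, median 0.14; Kdr at 0.42 ± 0.11; camera, adjusted p = 8.53e-05), as did immediate early genes (13 of 17; Nr4a1 at 1.17 ± 0.21 and Btg2 at 0.51 ± 0.075) and proliferation genes (15 of 17; Cenpa at 0.38 ± 0.15), both at a camera adjusted p of 0.00559. With an estimated correlation these 3 lists gave an adjusted p of 0.53, 0.63 and 0.77. Unfolded protein response genes (12 of 15 lower, median -0.18) and chemokines (18 of 23 lower; Ccl3, a macrophage chemokine, at -0.58 ± 0.11) shifted down with camera adjusted p of 0.000232 and 0.0127. Neither kept the call (adjusted p = 0.53 and 0.63 with an estimated correlation). The chemokine call was lost without HDAd-gE3 replicate 2 (camera, adjusted p = 0.093) and the proliferation call without HDAd-gE3 replicate 4 (0.82). Array weights ended both calls (chemokine median -0.0475, adjusted p = 0.14; proliferation 0.072), and a filter on dim genes the proliferation and immediate early calls (0.15 and 0.073). The replicate block ended the chemokine call (camera, adjusted p = 0.3). Without HDAd-gE3 replicate 4 the endothelial median was 0.211. The chemokine median of -0.204 was -0.0671 without HDAd-gE3 replicate 4, and that of the unfolded protein response -0.0619 without probe sets that may match several transcripts. By fry only the erythroid list passed; neutrophil, endothelial, immediate early, proliferation, unfolded protein response and chemokine genes did not (adjusted p = 0.11, 0.092, 0.23, 0.59, 0.078 and 0.2). The other 22 lists did not pass camera, with monocyte and macrophage genes nearest to the threshold (camera, adjusted p = 0.0677; lower on ranks, adjusted p = 0.036). Adjusted over the list alone, 3 leukocyte adhesion genes were higher and 1 lower, 1 interferon-stimulated, 1 MHC class II and 1 adipose gene were higher, and 3 matrix protease genes and 2 LXR targets were lower.

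Both comparisons with PBS called Pnpla3, Mlxipl and the predicted gene Gm14057 lower, and Sphk2 and Gm9706 higher, the predicted genes being named after their values were seen. They share the PBS arrays. Independent lists would share 0.0015 genes in the lower and 0.0069 in the higher direction. In 100 simulations of unchanged groups the top 12 and top 23 genes shared 2.3 on average and at most 6. Part of the overlap of 5 may come from the shared arrays, which are too few to split. Leaving out 1 array at a time gave between 0 and 21 limma calls for HDAd-gE3 against PBS. There were 0 without HDAd-gE3 replicate 3 or any 1 of the PBS arrays, with between 1638 and 2152 genes at an unadjusted p under 0.05. There were 1 without HDAd-gE3 replicate 2, 2 without HDAd-gE3 replicate 4, and 21, 16 and 15 without HDAd-0 replicate 3, 4 and 5. Without HDAd-gE3 replicate 4 and HDAd-0 replicate 5 together, 1 gene passed that was not among the 23, and 11 lists shifted.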

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

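The counts over other splits of the arrays were planned; the tests of liver, muscle, erythroid and endothelial genes and the look at control and unnamed probe sets were chosen after the results were seen.

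Control probe sets of 18S ribosomal RNA lie outside the gene comparisons and were higher with HDAd-0 than with PBS. The 3' probe set read 11.08 ± 0.21 against 9.337 ± 0.65 (log2, SD, n = 3; difference 1.74 ± 0.45, SE) and the middle one 13.35 ± 0.058 against 12.87 ± 0.11 (0.48 ± 0.13). Neither passed limma over the 64 control probe sets (adjusted p = 0.213 for both). On HDAd-gE3 replicates 2, 3 and 4 the 3' probe set read 10.61, 10.92 and 9.253, against 8.623 to 9.885 on the PBS arrays. Thus replicates 2 and 3 of HDAd-gE3 also lay above all PBS arrays. No explanation was tested.

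Liver and skeletal muscle genes were higher and cardiac genes lower with HDAd-0 than with PBS, and no gene of these lists is in another list. With the 3' minus 5' control signal in the fit, liver genes differed by 1.33 ± 0.27 (SE). This argues against RNA degradation as the whole cause for that list. Cardiac genes differed by -0.68 ± 0.31, against -0.847 ± 0.35 without the signal, and skeletal muscle genes by 0.984 ± 0.41, against 0.827 ± 0.42. Both are little over 2 SE with few residual degrees of freedom, so the test does not decide for these 2 lists. Other tissue carried over in differing amounts between pools is a candidate explanation. The aortas were taken from the sinus to the arch, and how liver tissue would enter such pools was not examined. Within groups the members of each list moved together from array to array. Their mean pairwise correlations were 0.53 for skeletal muscle, 0.57 for liver and 0.72 for cardiac genes. The upper limits from random lists of like size were 0.14, 0.16 and 0.17. Lists not made for a tissue moved together as well (oxidative phosphorylation 0.75, proliferation 0.7), and whether these follow carried-over tissue was not tested. Alb read 10.63 with HDAd-0 and 8.41 with PBS, but the abundant muscle genes Acta1 (8.91 and 9.73) and Ckm (7.89 and 8.23), which heart muscle also expresses, were not higher, and an effect of the vector on these genes stays open and was not tested.

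Erythroid genes were higher in both vector groups than with PBS. In HDAd-gE3 the mean of Mpo, Elane, Camp, Ngp and Ltf, all members of the neutrophil list, was higher by 1.81 ± 0.65 (SE; 1.06 ± 0.26 without replicate 4) beside 1.45 ± 0.26 for the erythroid list (1.22 ± 0.21), but neutrophil genes had been seen to be higher before these were chosen, so this does not count for precursor cells of the marrow type as the source, which stay open. In HDAd-0 the same 5 genes differed by -0.0813 ± 0.65 and the whole neutrophil list, tested for whole blood, by -0.0145 ± 0.31, beside 0.818 ± 0.26 for the erythroid list, which leaves both sources open at this spread. A version of the whole-blood test on 4 genes picked by hand (S100a8, S100a9, Cxcr2 and Csf3r; 0.00806 ± 0.19) would have argued against whole blood, and is not used because the test had been written down for the whole list. A response of blood formation to the vector was not tested.

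Endothelial genes were higher with HDAd-0 than with PBS by a list mean of 0.327 ± 0.057 (SE). With the 3' minus 5' signal in the fit it was 0.361 ± 0.040, which argues against RNA degradation as the whole cause. With liver and skeletal muscle means in the fit, to take out their vessels, it was 0.214 ± 0.10. That is only just over 2 SE with few residual degrees of freedom, so it does not decide. A lower share of smooth muscle would raise other cells alike, but endothelial exceeded macrophage genes by 0.208 ± 0.074. However, smooth muscle genes differed by -0.133 ± 0.018 and macrophage genes by 0.119 ± 0.026, both in the direction of that explanation. It stays open, since macrophage content may also vary separately. In HDAd-gE3, which carries the same kind of vector, the list mean exceeded PBS by 0.169 ± 0.057, and by 0.103 ± 0.044 with the 3' minus 5' signal. A response of the endothelium to the vector stays open and was not tested.

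The 6 arrays of each comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 1 gene for HDAd-gE3 against HDAd-0, 12 for HDAd-0 against PBS and 23 for HDAd-gE3 against PBS, and the highest other split 0 each time (limma). For lists the real counts were 16, 16 and 7 and the highest others 15, 14 and 9 (camera). As many lists as in the real split came from 1, 1 and 6 of the 10 splits, the real one included, and as many genes from 1 each time.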

How the results depend on the processing

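The fit with the 3' minus 5' control signal and the one without HDAd-gE3 replicate 4 and HDAd-0 replicate 5 were chosen after seeing the data; the other alternatives were planned. Counts below are in the order HDAd-gE3 against HDAd-0, HDAd-0 against PBS and HDAd-gE3 against PBS; limma called 1, 12 and 23 genes and camera 16, 16 and 7 lists. Unless said, the cause of a change was not tested.

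With only the 2 groups compared, which leaves fewer arrays to estimate the spread, 0, 0 and 13 genes passed (1787 and 2192 at an unadjusted p under 0.05 where 0 passed). Quantile normalization gave 1, 6 and 24, and median centring 0 (2192 unadjusted), 1 and 25. Without the genes below the median level 0 (1331 unadjusted), 22 and 144 passed and 12, 10 and 5 lists shifted, 22 lists being large enough to test. The mean of a gene's probe sets gave 1, 15 and 24 genes; without probe sets that may match several transcripts there were 1, 13 and 21, and 20, 15 and 11 lists. Every probe set gave 0 (5781 unadjusted), 4 and 1. Array weights gave 0 (3197 unadjusted), 17 and 804, and an intensity trend 1, 9 and 89. At least 1.5-fold gave 1, 6 and 21, and an adjusted p under 0.10 gave 1, 35 and 134.

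Replicate numbers as a block gave 0 genes in each comparison (2323, 2015 and 2178 unadjusted) and 12, 7 and 9 lists. The groups share only the numbers 3 and 4. Arrays of the same number correlated between -0.046 and 0.1 after removing group means, against -0.16 to 0.14 for other numbers. The groups hold different numbers, so removing group means spreads a shared batch over other pairs too. These values therefore cannot exclude a batch shared by number. An estimated correlation gave 0 lists in each comparison (4, 3 and 2 unadjusted), fry 8, 5 and 1, and ranks 16, 15 and 8.

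The 3' minus 5' covariate gave 0 (1836 unadjusted), 0 (2617 unadjusted) and 3 genes and 17, 13 and 14 lists. Without HDAd-gE3 replicate 4 and HDAd-0 replicate 5 there were 1, 1 and 1 genes, none among those called with all arrays, and 10, 15 and 11 lists.

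Leaving out 1 array gave 0 to 10, 0 to 31 and 0 to 21 genes and 11 to 18, 12 to 18 and 7 to 11 lists. The low gene counts had between 1608 and 2733 genes at an unadjusted p under 0.05. HDAd-0 replicate 4, without which the first 2 counts were 10 and 31, had the lowest array weight (0.343).

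Directions turned in the following cases. Ptov1 in HDAd-gE3 against HDAd-0 was -0.00504 without probe sets that may match several transcripts, and Thbs1 -0.0229 with the covariate. Fgf14 in HDAd-0 against PBS was -0.244 as the mean of its probe sets, and Il7 there -0.0389 without HDAd-0 replicate 4 (single arrays: -0.0389 to 0.113). Apoe in HDAd-gE3 against PBS was -0.000349 without HDAd-gE3 replicate 3 (single arrays: -0.000349 to 0.181) and -0.171 with the covariate. In HDAd-gE3 against HDAd-0 the adipose list had a median of -0.0579 without HDAd-0 replicate 4 and -0.163 with the covariate. The medians of cartilage and bone and of oxidative phosphorylation genes there were -0.0226 and -0.00682 with the covariate, and that of extracellular matrix genes -0.00939 without HDAd-0 replicate 3 and -0.00484 without both arrays. The interferon-stimulated list there turned relative to all genes, with medians of -0.0333 in the block fit, -0.0303 without HDAd-0 replicate 5 and -0.00323 without both arrays (single arrays: -0.282 to -0.0303).

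Of the called named genes, none reversed in the leave-outs, but 8 of 9, 83 of 90 and 132 of 162 such values lost their call. Of the values of called lists under alternatives other than leaving out 1 array, 53 of 205, 51 of 204 and 19 of 90 weakened until the call was lost, and 3 more of the 205 turned (2 of these without a call). The pseudocount alternative was not run, since the values are already log2. Signal near the floor limits dim genes such as Hba-a1.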

Other observations

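The gene groups here were chosen after Dbp, Hspa4l and Chordc1 had been seen, and these 3 genes are left out of the counts. All values are differences from PBS, whose arrays both vector groups share.

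Genes of the circadian clock, a group without a fixed list or a test of the group, had means above PBS for some members and below for others. Dbp, through which the group was found, was higher by 0.49 ± 0.068 with HDAd-0 and 0.48 ± 0.068 with HDAd-gE3 (log2, SE; limma, adjusted p = 0.0668 and 0.0547), and its dimmer probe set by 0.812 ± 0.077 and 0.781 ± 0.077, which passed with HDAd-0 in the fit of every probe set (0.0368) and not with HDAd-gE3 (0.0515). With HDAd-0, Arntl differed by -1.04 ± 0.18, Npas2 by -0.92 ± 0.24, Nfil3 by -0.61 ± 0.15, Cry1 by -0.52 ± 0.12 and Clock by -0.31 ± 0.062, while Per1 differed by 0.63 ± 0.17, Nr1d1 by 0.60 ± 0.18 and Ciart by 0.40 ± 0.079. With HDAd-gE3 the same genes had the same signs (Arntl -0.73, Cry1 -0.75, Nr1d1 0.78, Per1 0.54). Of 14 genes other than Dbp, 4 were higher and 5 lower at an unadjusted p under 0.05 with HDAd-0, and 5 and 3 with HDAd-gE3; none passed over all genes (limma, smallest adjusted p = 0.118 and 0.0847). Between the vector groups none was under 0.05 unadjusted. The hour of killing is not given in the labels, and a difference in it between PBS and the vector groups would enter every difference from PBS and is not excluded here.

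Chaperone genes, again without a fixed list or a test of the group and with the mitochondrial Hspd1 and Hspe1 among them, were lower with HDAd-0 in 15 of 15 cases, 6 of them at an unadjusted p under 0.05, with a median of -0.22, Dnaja1 at -0.36 ± 0.076 and Hsph1 at -0.24 ± 0.076. With HDAd-gE3 13 of 15 were lower, 3 at an unadjusted p under 0.05. None passed over all genes (limma, smallest adjusted p = 0.147 and 0.234). Outside the count, Hspa4l differed by -0.47 ± 0.063 and Chordc1 by -0.44 ± 0.062 with HDAd-0 (0.0618 and 0.0696).

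In the fit of every probe set, 1 further probe set without a gene name was lower with HDAd-0 than with PBS, at 5.217 against 6.092 (-0.88 ± 0.073; limma, adjusted p = 0.0368).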
